A study of Mus musculus with 6 samples.

How the data were processed

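The data were poly(A) RNA sequencing libraries from 20 mg pieces of frozen liver of 6 male mice aged 8 weeks, 3 WT (BALB_cJ) and 3 SCADD (BALB_cByJ), all kept on standard chow. The series design text describes the 3 animals of each group as biological replicates. RNA was isolated with a column kit and libraries were made with an NEBNext kit, per the labels' protocols. Reads were processed with STAR 2.7.6a and RSEM 1.3.3 on the mouse build GRCm38, per the submitters' processing notes. The annotation release was not given in the sources used here.

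For each library the authors deposited a STAR table of whole-number read counts per gene, with an unstranded and 2 stranded columns and 4 summary rows, and an RSEM table of expected counts and TPM per gene. The deposited counts were not normalised. The deposited TPM values were scaled by the authors' RSEM run to the same total in each library. The FPKM values in the deposited tables, scaled by the authors' RSEM run by gene length and library size, were not used here. By a rule fixed before the data were examined, the stranded column holding over 90% of stranded reads in each library was used. It was column 4, with 96.8% to 97.3% of them. The summary rows stayed out of library sizes and tests. Unmapped reads made up 13.6% to 36.6% of reads, multi-mapped reads 10.1% to 13.1% and reads in no gene 1.47% to 2.17%. The files hold 55487 genes, of which 55227 IDs matched GENCODE release M21, a GRCm38 annotation, which gave symbols, coordinates and exonic lengths. Gene totals were 26423882, 23991104 and 27148756 reads in WT replicates 1, 2 and 3, and 23912744, 20338645 and 16948986 in SCADD replicates 1, 2 and 3. A total of 3 counts over the WT group corresponded to 0.0389 CPM. Intervals and floors cover counting error only.

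Genes were kept by edgeR's filterByExpr with default settings (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, on all 6 libraries with the group as the only term. P-values were adjusted by Benjamini-Hochberg over the 13498 tested genes, and 0.05 was the threshold. Log2 fold changes use edgeR's prior count of 0.125, and SE is the log2 fold change divided by the square root of the quasi-likelihood F, an approximation. Where a group held 0 counts, folds were taken against a floor of 3 counts over the group. The lower limit of the exact 95% interval is given beside them. Where it held 1 to 3 counts, ratios of pooled counts are given with exact 95% intervals. Counts of replicate pairs differed by far more than sampling noise, with chi-square per degree of freedom of 37.1 to 130, and log CPM correlations were 0.974 to 0.988 within and 0.956 to 0.965 between groups.

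Lists of genes, 37 in all, were fixed before the data were examined. They cover fatty acid oxidation in mitochondria and peroxisomes, PPAR-alpha targets, ketone bodies, acyl-CoA enzymes, histone acyl factors, lipogenesis, cholesterol, bile acids, glucose, amino acids, xenobiotics, sex bias, Zhx2 targets, BALB substrain loci, stress responses, NRF2 targets, the respiratory chain, mitochondrial mRNAs, interferon, the acute phase, the clock, proliferation, handling, liver zonation and other cell types. Camera (limma 3.58.1, preset inter-gene correlation 0.01) compared each of the 35 lists with at least 3 tested genes with all other genes, and p-values were adjusted over these lists. The genes named were Acads, the tested members of the Zhx2 and substrain lists, and the 14 largest rises and 14 largest falls. The last 2 sets were taken among called genes with a mean of at least 1 CPM, groups that did not overlap and a symbol that was not a predicted, clone or pseudogene name. For each list up to 4 called members with the smallest p were added, or up to 2 where none was called. Other genes are described as chosen after their values were seen. Some genes taken by this rule are not reported here.

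Both steps were checked on simulated data, the gene test with 200 changed genes. Of 13274 simulated genes tested for SCADD against WT, edgeR recovered 10.1% of 1.5-fold, 58.1% of 2-fold and 93.2% of 4-fold changes, with 6 false among 105 calls. A simulated list of 20 genes raised 1.5-fold had a camera adjusted p of 2.62e-15 at the preset correlation, 0.0762 with an estimated correlation and 0.0448 with fry, and 0 of 99 unchanged lists were called by any of the 3. The simulated genes varied independently of each other. In that setting an estimated correlation from 6 libraries missed a true change of that size. How often the preset correlation falsely calls lists of correlated genes was not checked. Among the lists called in the data the estimated correlation ranged from 0.0556 for bile acid genes to 0.741 for the unfolded protein response.

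Alternatives were RLE and upper-quartile scaling, no filter or a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, RSEM expected counts rounded to whole numbers, the unstranded column, a test against a 1.5-fold change (glmTreat), a replicate block and leaving out each library. For the lists, an estimated correlation and fry were added. Leaving out the Mup genes before scaling and counting list members without the library with most unmapped reads, and without each other library, were added after the data were seen. Neighbouring genes were compared with 10000 random orders of the calls in Python 3.11.15. With 1000 orders this permutation test gave p = 0.396 on simulated random calls and p = 0.000999 on simulated pairs of neighbours. The borders of the Mup block were also drawn after the values were seen, around features near 0 in WT, and Mup6, at 0.0288 of its SCADD level, was left outside. The test of Mup3, Mup20 and Mup21 was set after their values were seen and was revised once. A version with a limit of 2 on the highest upper bound was replaced by a limit of 1 on each gene, and both versions led to the same reading.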

Results

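Gene expression was measured by RNA sequencing in the livers of 8-week-old male mice of 2 kinds, 3 animals each. Animals named WT belonged to the inbred substrain BALB_cJ. Animals named SCADD belonged to BALB_cByJ, a substrain deficient in short-chain acyl-CoA dehydrogenase, the mitochondrial enzyme that starts the oxidation of short-chain fatty acids. The title of the series places the comparison in the context of histone acylation and the transcriptional response to this deficiency. Genotype and substrain coincide in all 6 animals, so each difference below is one between the substrains, and the design holds no group that separates the enzyme defect from other substrain variants. Reads counted in genes totalled 23991104 to 27148756 per WT library and 16948986 to 23912744 per SCADD library. The share of unmapped reads was higher in the SCADD libraries, at 29.7% ± 6.12 (SD, n = 3) against 14.5% ± 1.58 (SD, n = 3) in WT. The exact two-sided permutation test gave p = 0.1 for this difference, the smallest value that 3 against 3 libraries allow. SCADD replicate 3 had the highest unmapped share, 36.6%, and the lowest gene total.

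Acads, the gene of the deficient enzyme (ENSMUSG00000029545, chromosome 5, 115110299 to 115119346, GRCm38), was expressed at a lower level in SCADD livers. In CPM, counts scaled to library size, its level was 185, 166 and 196 in WT replicates 1, 2 and 3, and 99.3, 104 and 96.96 CPM in SCADD replicates 1, 2 and 3. The means were 182 ± 15.2 and 100 ± 3.78 CPM (SD, n = 3 each), a log2 fold change of -0.86 (SE 0.13, edgeR adjusted p = 0.00407) or 0.550-fold, lower in each of the 3 SCADD libraries than in any WT library. The transcript was still present in the deficient livers, and each library named SCADD had the lower level. When the test asked for a change beyond 1.5-fold, the adjusted p of Acads was 0.244.

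**Figure D1:**
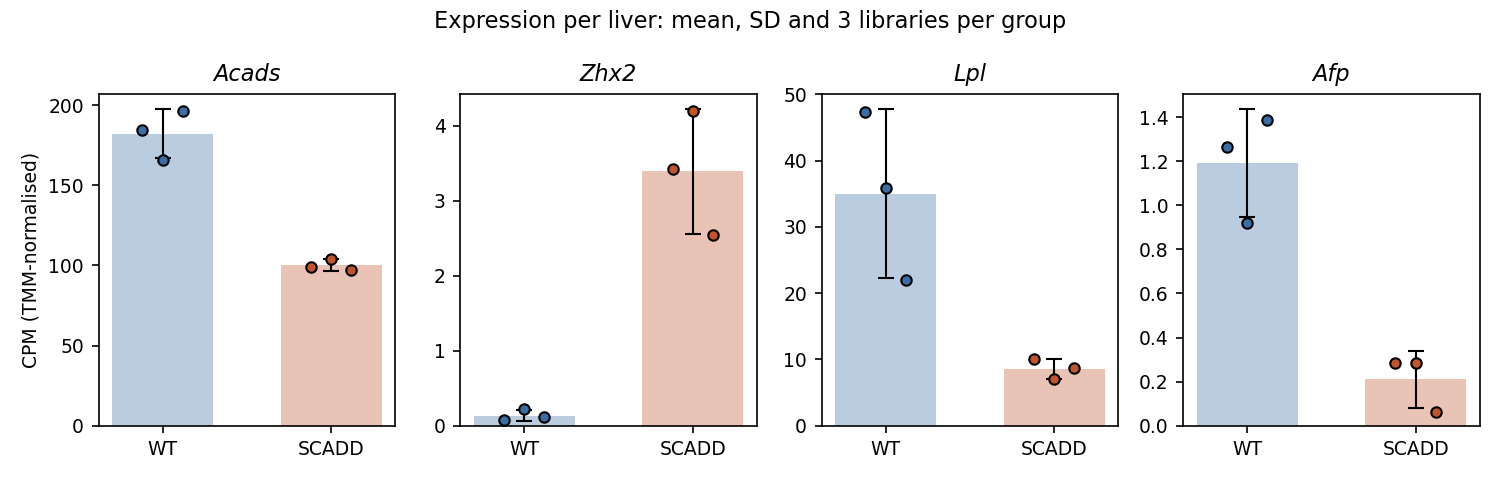
Normalised expression in CPM (vertical axes, each starting at 0) of Acads, Zhx2, Lpl and Afp in WT and SCADD livers. Bars show means of 3 libraries, lines the SD and points the libraries. Acads, Lpl and Afp lie lower and Zhx2 higher in each SCADD library than in any WT library.

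Across the transcriptome, 6 of 18 peroxisomal and 7 of 20 PPAR-alpha target genes rose in SCADD livers, as did 12 major urinary protein genes among the 14 largest named rises. Of the genes for amino acid breakdown 7 of 22 fell, as did 4 of 12 periportal genes and 4 of 15 genes of the unfolded protein response, the last falling to 0 without WT replicate 2, WT replicate 3 or SCADD replicate 1, to 2 without SCADD replicate 3 and rising to 8 without WT replicate 1. Camera called 10 of 35 gene lists at its preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.364; 2 had an unadjusted p under 0.05), and fry, which tests a list against no change rather than against other genes, called 6, 5 of them among these 10. Of 13498 genes tested, 947 differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 569 higher and 378 lower in SCADD. At least 2-fold differences were found for 261 of the higher and 184 of the lower genes. The groups did not overlap for 28.0% of the tested genes, against 10% by chance. The biological coefficient of variation was 17.6%. The principal component that carried most variance (57.6%) separated the groups, and the next (17.4%) set SCADD replicate 2 apart from SCADD replicate 3. Upper-quartile scaling changed the split to 470 higher and 482 lower genes. The number of called genes changed when 1 library was left out, with 395 without WT replicate 2, 460 without WT replicate 3, 517 without SCADD replicate 1 and 1590 without SCADD replicate 3. Without WT replicate 1, 403 were higher and 294 lower, and without SCADD replicate 2, 541 were higher and 374 lower. Leaving out any library also lowers the power of the test, so a lost call need not reflect that animal.

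The largest rises were in the major urinary protein (Mup) genes, which encode pheromone carriers made in the liver. By the rule fixed for naming genes, 12 of the 14 largest rises were Mup12, Mup9, Mup14, Mup1, Mup18, Mup2, Mup22, Mup7, Mup16, Mup17, Mup10 and Mup11. These genes lie on chromosome 4 between the start of Mup7 at 60066469 and the end of Mup-ps18 at 61883296, a block of 1.82 Mb. Its 29 annotated features with at least 10 counts, on both strands, held 142 unique counts in the 3 WT libraries together and 470004 in the 3 SCADD libraries, and 23 of them had 0 counts in WT. Mup12 had 0 counts over the WT group and 168691 over the SCADD group. Against a floor of 3 counts over the group it was 70164-fold higher, with a lower exact 95% counting limit of 57061. This pooled value leans on SCADD replicate 3, since Mup12 had 1615, 1183 and 6454 CPM in SCADD replicates 1, 2 and 3. Mup1 was 1670-fold and Mup22 334-fold higher by the same floor, with lower exact limits of 1357 and 271. Mup9 had 1 count in WT against 91667 in SCADD, a ratio of 114382 (95% exact counting interval 20529 to 4517910). SCADD replicate 3 held 267181 of the block counts, and Mup7 had 1028, 1007 and 4534 CPM in SCADD replicates 1, 2 and 3. Mup7 had 87 and Mup17 had 50 counts in WT, with log2 fold changes of 10.92 (SE 0.97, edgeR adjusted p = 0.00264) and 10.73 (SE 0.62, adjusted p = 9.33e-05). Members of this family are near-identical and share reads, so the value of each member is uncertain. Summed over the block, RSEM, which divides shared reads among copies, gave 7.36 ± 1.16 TPM in WT and 77518 ± 33335 TPM in SCADD (SD, n = 3 each). The borders of the block were drawn after the values were seen. Mup6, just before it, also rose, from 5 counts in WT to 139 in SCADD (log2 fold change 5.10, SE 0.71, adjusted p = 0.00254). The 3 highly expressed Mup genes after the block did not pass the test. Mup3 had a log2 fold change of -0.38 (SE 0.30, adjusted p = 0.507), Mup20 of -1.36 (SE 0.51, adjusted p = 0.172) and Mup21 of 0.71 (SE 0.56, adjusted p = 0.526). Mup21 had 317, 270 and 1032 CPM in SCADD replicates 1, 2 and 3. Its log2 fold change ran from -0.17 to 1.01 over the alternatives. Mup3, Mup6 and Mup21 were chosen after their values were seen. Calls were lost for Mup12 without SCADD replicate 1 or 2 (adjusted p 0.133 to 0.145) and for Mup14 without SCADD replicate 2 (0.0987). The same held for Mup16 without WT replicate 3 or SCADD replicate 2 (0.0652 to 0.0718) and for Mup18 without WT replicate 3, SCADD replicate 2 or SCADD replicate 3 (0.0741 to 0.298). Mup12 (0.163) and Mup18 (0.195) also lost it without a filter and Mup16 with limma-voom (0.0705).

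**Figure D2:**
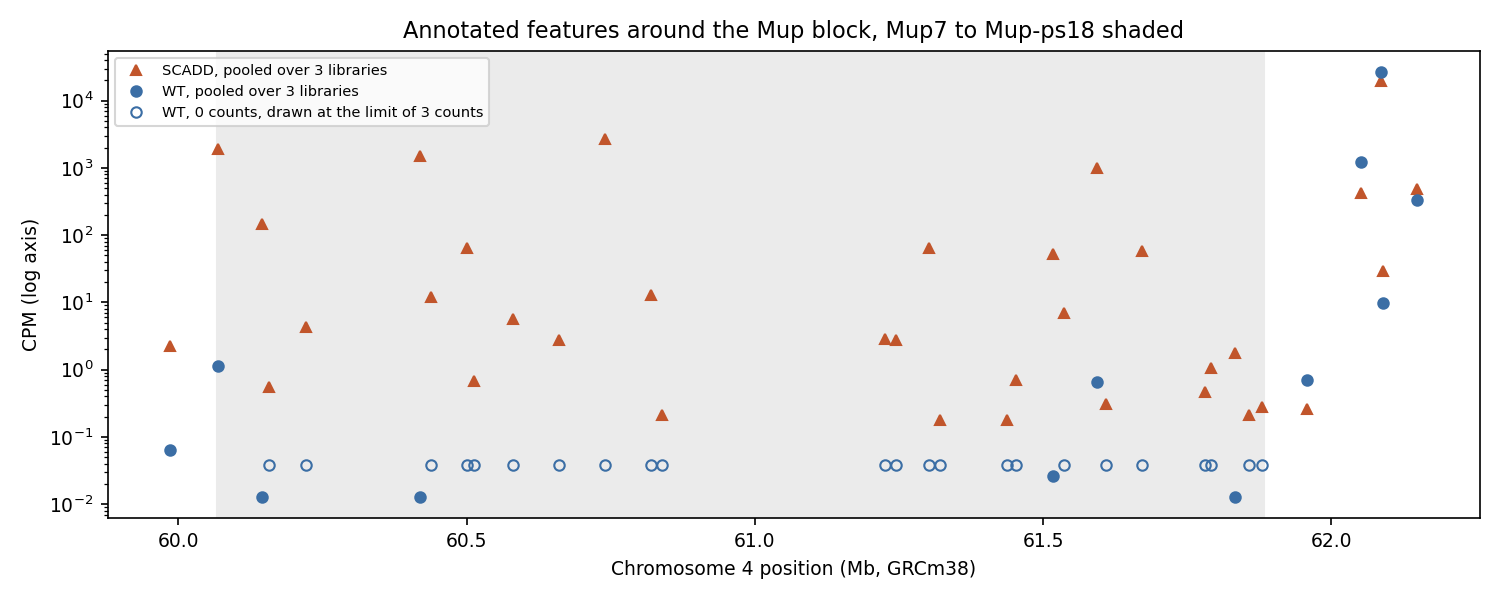
Expression of annotated features (CPM on a log axis, pooled over 3 libraries per group) by position on chromosome 4 in Mb, GRCm38, with the block from Mup7 to Mup-ps18 shaded. Open circles are features with 0 counts in WT, drawn at the limit of 3 counts. Within the block 23 of 29 features have 0 WT counts, whereas Mup20, Mup3 and Mup21 to its right have counts in both groups.

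Genes outside the Mup family were also among the largest changes. Dnah17, an axonemal dynein, had 0 counts in WT and 680 in SCADD. It was 283-fold higher against the floor of 3 counts, with a lower exact 95% counting limit of 229. Obp2a, an odorant-binding protein, rose from 0.0667 ± 0.0591 to 25.4 ± 12.0 CPM (SD, n = 3 each; edgeR adjusted p = 0.00015). Among the falls named by the rule, Iqca had 464 counts in WT and 2 in SCADD, a ratio of 0.00538 (95% exact counting interval 0.000649 to 0.0195). Dnaic1, another dynein gene, fell by 7.02 on the log2 scale (SE 0.31, adjusted p = 1.92e-06). Its neighbour Enho, which encodes the secreted peptide adropin, fell from 102 ± 5.81 to 9.17 ± 0.419 CPM (adjusted p = 8.05e-07). Metallothionein Mt2 fell from 198 ± 15.4 to 16.0 ± 9.54 CPM (adjusted p = 0.0101), Sucnr1, the succinate receptor, from 47.0 ± 15.1 to 5.75 ± 1.70 CPM (adjusted p = 0.000433), and Selenbp2 from 1568 ± 604 to 225 ± 85.2 CPM (adjusted p = 0.00207). Other falls named by the rule were Ntrk2, Cox6b2, Tspyl4, Eif4ebp3, Lysmd2, Erp27 and Cyp39a1, with log2 fold changes from -4.71 for Ntrk2 to -2.83 for Cyp39a1. Without SCADD replicate 3, the calls of Mt2 (adjusted p = 0.0811), Selenbp2 (0.0578) and Ntrk2 (0.0630) were lost, and without SCADD replicate 2 that of Cyp39a1 (0.127). Calls were also lost without a filter for Mt2 (0.058) and Cyp39a1 (0.0912), with limma-voom for Ntrk2 (0.0581) and with RSEM counts for Eif4ebp3 (0.0774).

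Some genes of fatty acid oxidation and some PPAR-alpha targets rose in SCADD livers. Of 20 tested PPAR-alpha target genes, 7 rose and 0 fell, and 11 rose when adjusted over the list alone or with DESeq2. Vnn1, a pantetheinase, rose from 95.8 ± 40.1 to 751 ± 125 CPM (log2 fold change 2.97, SE 0.29, edgeR adjusted p = 0.000307). The acyl-CoA thioesterase gene Acot1 rose by 3.15 (SE 0.32, adjusted p = 0.00066), Acot2 by 3.19 (SE 0.34, adjusted p = 0.00207) and Fitm1, which acts in lipid droplet formation, by 4.08 (SE 0.34, adjusted p = 0.000268) on the log2 scale. Members that did not pass, chosen after their values were seen, included Pdk4, with a log2 fold change of 2.61 (SE 0.66, adjusted p = 0.0788), and Plin2, with 0.14 (SE 0.19, adjusted p = 0.728). Camera called the list higher than other genes at adjusted p = 6.74e-09, and gave adjusted p = 0.371 with an estimated correlation. In peroxisomal fatty acid oxidation, 6 of 18 genes rose and 0 fell, and 7 rose when adjusted over the list alone. They included Acot4 (log2 fold change 2.32, SE 0.15, adjusted p = 1.87e-05), the peroxisome proliferation factor Pex11a (1.88, SE 0.16, adjusted p = 0.000122), Ehhadh (2.15, SE 0.34, adjusted p = 0.00617) and the thiolase Acaa1b (1.52, SE 0.24, adjusted p = 0.00431). The list had a camera adjusted p of 1.38e-06, and adjusted p = 0.371 with an estimated correlation. In mitochondrial fatty acid oxidation without Acads, 3 of 22 genes rose and 0 fell, 6 rose with DESeq2, and 7 rose when adjusted over the list alone. These were the carnitine transporter Slc22a5 (log2 fold change 0.83, SE 0.14, adjusted p = 0.0064), the carnitine-acylcarnitine carrier Slc25a20 (0.78, SE 0.13, adjusted p = 0.00681) and the medium-chain dehydrogenase Acadm (0.70, SE 0.17, adjusted p = 0.0304). For this list camera gave an adjusted p of 0.0076, 0.0542 without SCADD replicate 1, and adjusted p = 0.571 with an estimated correlation and 0.056 by fry. Leaving out a library ended the call of Ehhadh (SCADD replicate 3, adjusted p = 0.0778) and of Acadm (WT replicate 1, 2 or 3 or SCADD replicate 1, 0.0941 to 0.146). Only 5 PPAR-alpha, 4 peroxisomal and 2 mitochondrial oxidation genes rose without WT replicate 2, WT replicate 3 or SCADD replicate 1. Against a 1.5-fold change the numbers were 5, 4 and 0. None of 8 ketone body genes passed with edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 1 higher. The lactate and ketone transporter Slc16a7 had a log2 fold change of 0.49 (SE 0.18, adjusted p = 0.131), the camera adjusted p of the list was 0.271, and 1 gene rose without SCADD replicate 3.

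**Figure D3:**
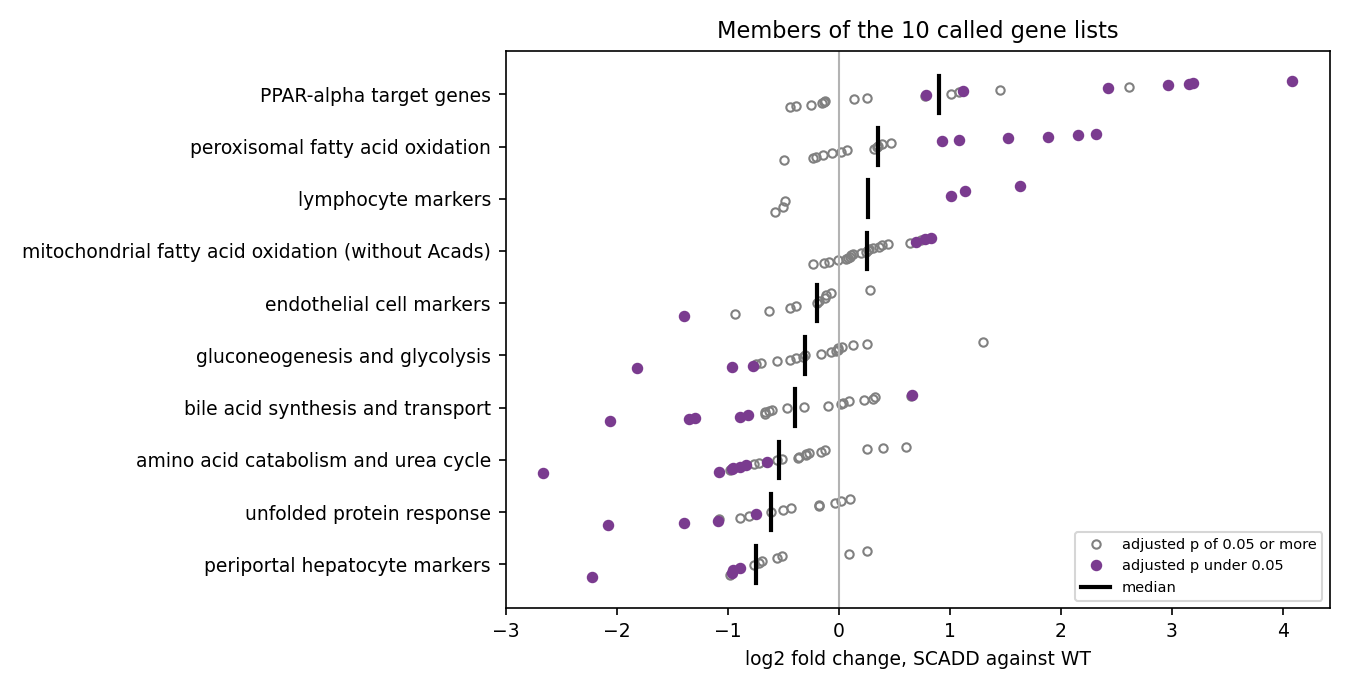
Log2 fold changes (horizontal axis, SCADD against WT) of the tested members of the 10 lists called by camera at its preset correlation. Filled points passed the edgeR test at an adjusted p under 0.05, open points did not, and bars mark medians. The median is highest for PPAR-alpha target genes, 0.90, and lowest for periportal markers, -0.74.

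Some genes for amino acid breakdown and ureagenesis fell in SCADD livers. Of 22 tested, 7 fell and 0 rose, and when adjusted over the list alone 11 fell and 1 rose. Got1, the cytosolic aspartate aminotransferase, fell from 116 ± 32.3 to 18.3 ± 3.86 CPM (log2 fold change -2.66, SE 0.23, edgeR adjusted p = 0.000148). The urea cycle genes Asl (-1.08, SE 0.14, adjusted p = 0.00149) and Cps1 (-0.97, SE 0.17, adjusted p = 0.00728) also fell, as did the serine dehydratase-like gene Sdsl (-0.89, SE 0.16, adjusted p = 0.0103). The amino acid list had a camera adjusted p of 5.89e-08, and adjusted p = 0.364 with an estimated correlation. Of 12 periportal hepatocyte markers, 4 fell and 0 rose, 7 fell with DESeq2 and 6 with limma-voom, and 7 fell when adjusted over the list alone. They were Cdh1, the cell adhesion gene of E-cadherin (-2.22, SE 0.32, adjusted p = 0.00283), Cps1, Sdsl and Sds (-0.96, SE 0.19, adjusted p = 0.0137), so 3 of the 4 also belong to the amino acid list. The periportal list had a camera adjusted p of 1.38e-06, and adjusted p = 0.364 with an estimated correlation. Among 11 pericentral markers, 3 rose and 2 fell, in both counts, and the list was not called (camera adjusted p = 0.614). The glutamate transporter Slc1a2 rose by 0.83 (SE 0.16, adjusted p = 0.0111) and Lgr5, a Wnt pathway receptor, fell by 1.06 (SE 0.25, adjusted p = 0.0319) on the log2 scale. Slc1a2 lost its call without WT replicate 3 (0.0586) and Lgr5 without any library but SCADD replicate 3 (0.058 to 0.103). Without WT replicate 2 or 3, 1 pericentral gene rose and 0 fell, without SCADD replicate 1, 0 fell, and without WT replicate 1 or SCADD replicate 2, 1 fell. Without WT replicate 2, 2 amino acid genes and 1 periportal gene fell, without SCADD replicate 1, 4 amino acid genes fell, and without SCADD replicate 2, 11 amino acid and 9 periportal genes fell. An amino acid gene rose without SCADD replicate 3, with DESeq2, with limma-voom and with the replicate block. The calls of Cps1 (adjusted p = 0.0504), Sdsl (0.0563) and Sds (0.0541 to 0.0785) were lost without WT replicate 2, and that of Sds also without SCADD replicate 1.

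Some bile acid and glucose genes fell as well. In bile acid synthesis and transport, 5 of 20 genes fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. Cyp7b1, an oxysterol hydroxylase, fell from 331 ± 125 to 79.7 ± 28.2 CPM (log2 fold change -2.06, SE 0.34, edgeR adjusted p = 0.0101), and the bile acid-CoA ligase gene Slc27a5 to 0.407-fold (SE of the log2 value 0.19, adjusted p = 0.00285). The transporters Slco1a4 (-1.35, SE 0.23, adjusted p = 0.00738) and Abcg5 (-0.89, SE 0.17, adjusted p = 0.0104) also fell. The rising member was the phospholipid exporter Abcb4, chosen after its values were seen, with a log2 fold change of 0.66 (SE 0.16, adjusted p = 0.0315). Cyp7a1, the rate-limiting enzyme of bile acid synthesis and also chosen after its values were seen, had a log2 fold change of -0.66 (SE 0.25, adjusted p = 0.146). Camera called the bile acid list at an adjusted p of 0.00651, and adjusted p = 0.371 with an estimated correlation. Without WT replicate 2, 3 genes of the list fell and the call of Abcg5 was lost (adjusted p = 0.0527). The number that rose was 0 without WT replicate 2 or 3 or SCADD replicate 1 or 2, and 2 without SCADD replicate 3. In gluconeogenesis and glycolysis, 3 of 19 genes fell and 0 rose, and 4 fell when adjusted over the list alone. They were the coactivator Ppargc1a (-1.82, SE 0.30, adjusted p = 0.00744), the kinase-phosphatase Pfkfb1 (-0.96, SE 0.20, adjusted p = 0.0165) and the glycogen synthase Gys2 (-0.77, SE 0.19, adjusted p = 0.0334). The camera adjusted p was 0.0217, 0.212 without SCADD replicate 3, and adjusted p = 0.606 with an estimated correlation. Calls were lost for Ppargc1a without SCADD replicate 3 (adjusted p = 0.0516), for Pfkfb1 without WT replicate 2 or 3 (0.0539 to 0.0617) and for Gys2 without any WT replicate or SCADD replicate 1 (0.0676 to 0.136). The number of fallen genes was 1 without WT replicate 2 or WT replicate 3 and 5 without SCADD replicate 2.

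Of 15 tested genes of the unfolded protein response 4 fell, all chaperone or secretory pathway genes, and 0 rose, and 9 fell when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1034 ± 332 to 485 ± 23.8 CPM (log2 fold change -1.09, SE 0.23, edgeR adjusted p = 0.0185). Sdf2l1 (-2.07, SE 0.47, adjusted p = 0.0491), Hsp90b1 (-0.75, SE 0.19, adjusted p = 0.039) and Manf (-1.39, SE 0.32, adjusted p = 0.0394) were the others. The camera adjusted p was 0.000134, and adjusted p = 0.617 with an estimated correlation and 0.241 by fry. The number of fallen members varied from 0 without WT replicate 2, WT replicate 3 or SCADD replicate 1 to 8 without WT replicate 1, with 2 without SCADD replicate 3. Hspa5 lost its call without WT replicate 2 or 3 or SCADD replicate 1 (0.0534 to 0.101), Hsp90b1 without these or SCADD replicate 2 (0.0594 to 0.161), and Sdf2l1 and Manf without any library but WT replicate 1 (0.0544 to 0.215 and 0.101 to 0.194). With limma-voom 2 genes fell and the calls of Sdf2l1 (0.107) and Manf (0.0588) were lost, that of Sdf2l1 also without a filter (0.105) and with RSEM counts (0.0534), while DESeq2 called 8 lower. In the integrated stress response, 1 of 14 genes rose and 1 fell, both also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.175). Gdf15, a stress-induced cytokine, rose from 1.55 ± 0.349 to 6.46 ± 2.47 CPM (log2 fold change 2.04, SE 0.30, adjusted p = 0.00322), while Chac1, at under 1 CPM, fell by 1.34 (SE 0.35, adjusted p = 0.0438) and lost its call without any single library (0.0597 to 0.171), with DESeq2 (0.09) and with RSEM counts (0.0641). Without SCADD replicate 3, 3 genes of that list rose, and with DESeq2 2 rose and 0 fell. Among 14 NRF2 target genes, 2 rose and 2 fell (camera adjusted p = 0.738), and 6 rose and 3 fell when adjusted over the list alone. With DESeq2 4 NRF2 targets rose. The falls were the metallothioneins Mt2 and Mt1 (-2.37, SE 0.29, adjusted p = 0.00218, lost without SCADD replicate 3 at 0.0512). The rises were the reductases Gsr (0.56, SE 0.12, adjusted p = 0.0214) and Txnrd1 (0.64, SE 0.14, adjusted p = 0.0232). Gsr lost its call without any WT replicate or SCADD replicate 1 (0.0526 to 0.116), and Txnrd1 without WT replicate 1, WT replicate 2 or SCADD replicate 1 (0.0569 to 0.109). The number of NRF2 targets that rose was 0 without WT replicate 1, WT replicate 2 or SCADD replicate 1, 1 without WT replicate 3 and 4 without SCADD replicate 3, when 0 fell.

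The lists of lipid synthesis, acyl-CoA enzymes, histone acyl factors, the respiratory chain and mitochondrial mRNAs were not called. Camera asks for 1 shared direction. Fry's test against no change in either direction gave unadjusted p = 9.75e-06 for lipogenesis, 0.000482 for acyl-CoA enzymes and 0.000714 for histone acyl factors. It gave 0.122 for the respiratory chain, 0.304 for mitochondrial mRNAs and 0.426 for cholesterol genes. In de novo lipogenesis, 4 of 17 genes rose, 5 when adjusted over the list alone, and 0 fell (camera adjusted p = 0.0721). Dgat2, a triglyceride synthesis enzyme, rose by 1.14 (SE 0.15, edgeR adjusted p = 0.00207), Gpam by 0.63 (SE 0.14, adjusted p = 0.024), Acacb by 0.94 (SE 0.23, adjusted p = 0.0352) and the desaturase gene Scd1 by 3.03 (SE 0.63, adjusted p = 0.0475) on the log2 scale. Only 1 gene rose without WT replicate 2, WT replicate 3 or SCADD replicate 1, and 1 fell without SCADD replicate 2. The lipogenesis list passed without WT replicate 1 (0.0431), WT replicate 3 (0.016) or SCADD replicate 3 (0.0235). Scd1 lost its call without any library but WT replicate 1 (0.0548 to 0.185), Gpam without any WT replicate or SCADD replicate 1 (0.0588 to 0.132), and Acacb without WT replicate 2 or 3 or SCADD replicate 1 or 3 (0.0805 to 0.141). Scd1 also lost it without a filter (0.149) and Acacb with RSEM counts (0.0658). In cholesterol synthesis and uptake, Hsd17b7 (0.61, SE 0.15, adjusted p = 0.0397) was the 1 of 24 genes that rose, 0 when adjusted over the list alone. It lost its call with upper-quartile scaling (0.0599) and without WT replicate 2, WT replicate 3 or SCADD replicate 1 (0.127 to 0.161). That list had a camera adjusted p of 0.738 and of 0.00427 without WT replicate 3, when 2 rose, 0 rose without WT replicate 2 or SCADD replicate 1, and 1 fell without WT replicate 1. Among 28 short-chain and branched-chain acyl-CoA enzymes, 1 rose and 1 fell, in both counts, and camera's adjusted p was 0.738. Without WT replicate 1, 2 of them rose, and with DESeq2 2 fell. Acss3, an acyl-CoA synthetase for propionate and acetate, rose by 1.47 (SE 0.15, adjusted p = 0.000357). Mut, the methylmalonyl-CoA mutase, fell by 0.66 (SE 0.16, adjusted p = 0.0302), a call lost without any WT replicate or SCADD replicate 1 (0.0534 to 0.138). None of 35 histone acyl writers, erasers and readers passed by edgeR, DESeq2 or limma-voom, 1 rose with RSEM counts, and 7 had an unadjusted edgeR p under 0.05. Log2 fold changes in this histone list ran from -0.49 to 0.51. On simulated data edgeR recovered only 10.1% of 1.5-fold changes, so changes of this size can be missed. Kansl2 had a log2 fold change of 0.46 (SE 0.13, adjusted p = 0.0574), the camera adjusted p of the list was 0.614, and 2 genes rose without SCADD replicate 3. Of 27 nuclear-encoded respiratory chain genes none passed by edgeR, DESeq2 or limma-voom and 2 had an unadjusted edgeR p under 0.05. Their log2 fold changes ran from -0.32 for Ndufs8 to 0.21 for Ndufa10, chosen after its value was seen (camera adjusted p = 0.25). Of 13 mitochondrially encoded mRNAs none passed with edgeR, 1 had an unadjusted p under 0.05, and DESeq2 called 1 lower. The complex I gene mt-Nd5 had a log2 fold change of -0.46 (SE 0.18, adjusted p = 0.161), and camera's adjusted p was 0.469. Without SCADD replicate 3 that list had 2 lower genes and a camera adjusted p of 0.0193.

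Some of the genes known to differ between the BALB substrains changed, with 3 of 7 tested substrain loci passing. Zhx2, a repressor of fetal liver genes that is disrupted in BALB/cJ, had 0.135 ± 0.0755 CPM in WT and 3.39 ± 0.828 CPM in SCADD (log2 fold change 4.65, SE 0.39, edgeR adjusted p = 0.000105). Of 10 tested genes that Zhx2 regulates, 2 rose and 3 fell, and 2 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.0619). Camera asks for 1 shared direction, so it cannot decide whether a list with rises and falls changed. Fry's test against no change in either direction gave an unadjusted p = 0.000106 for this list. Lpl, lipoprotein lipase, fell from 35.04 ± 12.7 to 8.59 ± 1.49 CPM (log2 fold change -2.03, SE 0.27, adjusted p = 0.00262). Hsd3b5, a steroid dehydrogenase, fell by 2.57 (SE 0.25, adjusted p = 0.000317). The fetal gene Afp fell from 1.19 ± 0.244 to 0.210 ± 0.128 CPM (adjusted p = 0.0092). That fall of Afp was not found in other counts of the same reads, where unstranded counts gave a log2 fold change of 0.77 (adjusted p = 0.0827) and RSEM counts -0.49 (adjusted p = 0.349). Mup11 and Cyp4a12a (0.63, SE 0.15, adjusted p = 0.0301) rose. Gpc3 (-1.18, SE 0.69, adjusted p = 0.348), Cyp8b1 (-0.60, SE 0.20, adjusted p = 0.103), Elovl3 (0.84, SE 0.54, adjusted p = 0.431), Cyp2a4 (0.31, SE 1.47, adjusted p = 0.938) and Mup20 did not pass, and H19 was too low to test. Cyp2a4 had 1.02, 28.4 and 1.24 CPM in SCADD replicates 1, 2 and 3. Its log2 fold change ran from -2.90 to 1.28 over the alternatives. Cyp4a12a lost its call without any WT replicate or SCADD replicate 1 or 2 (0.0558 to 0.134), and the list passed at adjusted p of 0.00264 to 0.0167 without any WT replicate or SCADD replicate 1, when 1 gene rose. Of 7 tested substrain loci, Zhx2 rose and the class I genes H2-Q2 (-0.74, SE 0.17, adjusted p = 0.028) and H2-Q7 (-0.87, SE 0.23, adjusted p = 0.0461) fell (camera adjusted p = 0.551). When adjusted over the list alone, 1 rose and 5 fell. For these loci too, which moved both ways, fry's test in either direction gave a lower value (unadjusted p = 3.4e-06). H2-Q1, H2-Q4, H2-Q6 and H2-Q10 did not pass, with log2 fold changes of -0.52, -0.48, -0.61 and 0.13. These genes share near-identical sequence, and H2-Q2 lost its call without any library but SCADD replicate 3 (0.0545 to 0.111) and H2-Q7 without any single library (0.057 to 0.166). With RSEM counts the calls of H2-Q2 (0.0561) and H2-Q7 (0.114) were lost, and that of H2-Q7 also with DESeq2 (0.0532) and limma-voom (0.0505).

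Sex-biased, xenobiotic and clock genes moved in both directions or rarely passed. Of 19 male-biased genes 3 rose and 3 fell (camera adjusted p = 0.614), in both counts, with Hsd3b5, Selenbp2 and Cyp7b1 among the falls and Mup7 and Mup11 among the rises. Of 16 female-biased genes 1 rose and 1 fell, 2 and 2 when adjusted over the list alone (camera adjusted p = 0.753), with 2 falls without WT replicate 1 or SCADD replicate 1 or with RSEM counts, and 2 rises and 2 falls with DESeq2. Acot3 rose from 6.90 ± 1.40 to 124 ± 19.5 CPM (log2 fold change 4.17, SE 0.20, edgeR adjusted p = 2.32e-06). Among 25 xenobiotic metabolism genes, 4 rose and 2 fell, 5 and 3 when adjusted over the list alone (camera adjusted p = 0.45). The nuclear receptor gene Nr1i3, which encodes CAR, rose by 0.97 (SE 0.16, adjusted p = 0.00617) and the heme synthesis gene Alas1 by 1.08 (SE 0.17, adjusted p = 0.00498). Cyp2c54 fell by 1.23 (SE 0.24, adjusted p = 0.012) and Cyp3a13 by 0.69 (SE 0.16, adjusted p = 0.0246). Those falls were lost without WT replicate 2 or SCADD replicate 1 for Cyp2c54 (0.0514 to 0.0616), and also without WT replicate 3 for Cyp3a13 (0.0757 to 0.114). Without WT replicate 1, 2 xenobiotic genes rose and 4 fell, without WT replicate 2, 2 rose and 0 fell, without WT replicate 3, 1 fell and without SCADD replicate 1, 0 fell. In the circadian clock list 1 of 19 genes rose, in both counts, Hlf by 0.77 (SE 0.18, adjusted p = 0.0269), a call lost without WT replicate 1, WT replicate 2 or SCADD replicate 2 (0.0576 to 0.124). The clock list had a camera adjusted p of 0.17, of 0.00264 without WT replicate 3, when 3 genes rose, and of 0.0178 without SCADD replicate 1, when 2 rose, as with DESeq2. The median, mean and camera direction differed in sign for the male-biased, female-biased, Zhx2-regulated, substrain, NRF2, acute-phase, cholesterol and acyl-CoA enzyme lists.

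Among markers of other cells in the tissue, 3 immunoglobulin genes and the erythroid gene Alas2 rose and the endothelial gene Lyve1 fell. Of 6 tested lymphocyte markers, 3 rose and 0 fell, in both counts. The rises were the immunoglobulin genes Ighm (log2 fold change 1.13, SE 0.15, edgeR adjusted p = 0.00209), Igkc (1.01, SE 0.17, adjusted p = 0.00694) and Jchain (1.63, SE 0.35, adjusted p = 0.0268). The 3 markers that did not pass had log2 fold changes not above 0, the lowest -0.57. The lymphocyte list had a camera adjusted p of 0.0309, 0.204 without WT replicate 3, and adjusted p = 0.371 with an estimated correlation. Of 11 endothelial markers, Lyve1 fell by 1.40 (SE 0.29, adjusted p = 0.0152) and 0 rose, in both counts. The endothelial list had a camera adjusted p of 0.0411, 0.155 without SCADD replicate 1, and adjusted p = 0.617 with an estimated correlation. Jchain lost its call without any WT replicate (0.072 to 0.107) and Lyve1 without WT replicate 2 or 3 (0.0625 to 0.0703), and 2 endothelial markers fell without SCADD replicate 3. The erythroid gene Alas2 rose by 1.13 (SE 0.17, adjusted p = 0.00357), 1 of 5 in its list, with a camera adjusted p of 0.121 that became 1.18e-05 without SCADD replicate 2, when 5 rose. By edgeR, DESeq2 and limma-voom none of 11 Kupffer, 12 stellate, 3 cholangiocyte, 4 neutrophil and monocyte and 1 adipocyte markers passed. Their numbers at an unadjusted edgeR p under 0.05 were 2, 1, 2, 0 and 0, and no pancreatic acinar marker was expressed enough to test. Adjusted over its list alone, no marker of these passed except 2 cholangiocyte markers, which were lower. Camera's adjusted p was 0.551 for Kupffer, 0.581 for stellate, 0.0897 for cholangiocyte and 0.614 for neutrophil and monocyte markers. C1qa had a log2 fold change of -0.41, Ecm1 of -0.43, Epcam of -1.13, S100a8 of 0.92 and Adipoq of -1.89, with adjusted p of 0.176, 0.11, 0.0773, 0.296 and 0.441. Single libraries weighed on the last 2. Adipoq had 4.67, 0.306 and 0.300 CPM in WT replicates 1, 2 and 3. S100a8 had 1.02, 0.802 and 3.10 CPM in SCADD replicates 1, 2 and 3. Over the alternatives their log2 fold changes ran from -2.39 to 0.64 for Adipoq and from 0.14 to 1.24 for S100a8. Without SCADD replicate 3, 2 Kupffer and 2 cholangiocyte markers fell, with camera adjusted p of 0.0409 and 0.0228. Cholangiocyte markers also passed without WT replicate 2 (0.0303) and SCADD replicate 1 (0.0178).

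Inflammation, handling and proliferation lists were not called either. Of 25 interferon-stimulated genes 1 rose and 2 fell, in both counts (camera adjusted p = 0.0657). Usp18 fell by 0.95 (SE 0.16, edgeR adjusted p = 0.00668). Ifit1 fell by 0.59 (SE 0.13, adjusted p = 0.0261) and Iigp1 rose by 0.60 (SE 0.15, adjusted p = 0.0371), both lost without any WT replicate or SCADD replicate 1 (0.0741 to 0.126 and 0.106 to 0.162), and Iigp1 also with upper-quartile scaling (0.0518), when 0 rose. The list passed without WT replicate 2 (0.0456), WT replicate 3 (0.039) or SCADD replicate 2 (0.000777), when 5 genes fell. Of 20 acute-phase genes 1 rose and 1 fell, 2 and 5 with DESeq2, 2 and 4 when adjusted over the list alone (camera adjusted p = 0.73). Lcn2 rose by 1.61 (SE 0.29, adjusted p = 0.0085) and Itih3 fell by 0.69 (SE 0.18, adjusted p = 0.0443), lost without any library but SCADD replicate 3 (0.0523 to 0.149) and with RSEM counts (0.0517). Without WT replicate 3, 2 acute-phase genes rose, and without SCADD replicate 3, with upper-quartile scaling or with limma-voom, 2 fell. Among 12 immediate-early genes, which respond to handling, 1 rose and 2 fell, in both counts (camera adjusted p = 0.619). Jun rose by 1.57 (SE 0.29, adjusted p = 0.013), and Hspa1a (-3.37, SE 0.70, adjusted p = 0.0166) and Btg2 (-0.82, SE 0.18, adjusted p = 0.0186) fell. Their calls were lost without WT replicate 2, WT replicate 3 or SCADD replicate 3 for Jun (0.0577 to 0.0656), without WT replicate 2 or 3 for Hspa1a (0.0608 to 0.0748; 0.0868 with RSEM counts), and without WT replicate 3 or SCADD replicate 1 for Btg2 (0.0801 to 0.0898). None of 7 proliferation genes passed by edgeR, DESeq2 or limma-voom, 1 had an unadjusted edgeR p under 0.05, and camera's adjusted p was 0.73. Cdk1 had a log2 fold change of 0.82 (SE 0.30, adjusted p = 0.135).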

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

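The tests of the Mup block and of the unmapped excess per Mup read were chosen after the results were seen, whereas the tests of Zhx2, of gene length and of other splits of the libraries were written before.

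Unmapped reads, which no comparison uses, made up 29.7% of reads in SCADD libraries, above the level of each WT library. RSEM counts over the Mup block made up 2.61% of reads in SCADD libraries, above each WT library.

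The higher unmapped share in SCADD was weighed against lower RNA quality and against Mup reads that match more gene copies than the aligner reports. Lower RNA quality in SCADD would make log2 fold changes fall with exonic length, but Spearman's rho across 13491 genes, which are not independent replicates, was 0.127 (95% bootstrap interval 0.112 to 0.143), above the limit of -0.1 set for it. Longer genes thus tended to be somewhat higher in SCADD. The cause of this trend was not tested, and no gene or list test adjusted for it. The unmapped excess over the WT mean, per percent of reads that RSEM gave to the Mup block, was 5.71, 6.31 and 5.62 in SCADD replicates 1, 2 and 3, a highest-over-lowest ratio of 1.12. A candidate explanation is therefore that much of the excess is Mup reads set aside as unmapped. Its sequence was not analysed here, so other sources stay open, and a biological difference in Mup output between the substrains would produce the same reads.

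The near absence of Mup block reads in WT was weighed against shared reads, an effect of Zhx2 on the whole family and a substrain difference of the block. Loss of shared reads is argued against by RSEM, which gave WT 0.013% of the SCADD level over the block, although reads matching more copies than the aligner reports would be missing from RSEM as well. Such reads would count as unmapped, and that share was lower in each WT library than in any SCADD library (means 14.5% and 29.7%). Multi-mapped reads were alike, at 11.7% in WT and 11.4% in SCADD. These shares also argue against a loss confined to WT, though the unmapped sequence was not analysed. A Zhx2 effect on all Mup genes alike is argued against by Mup3, Mup20 and Mup21 beyond the block, where 2 of 3 had an upper limit of the log2 fold change (plus 2 SE) under 1. A substrain difference covering the block is consistent with the highest WT level over its 29 features, 0.722% of SCADD, on both strands and with pseudogenes included, but the borders were drawn after the values were seen and Mup6 just outside, at 0.0288 of its SCADD level, would not have met the limit of 1%. Whether the block is missing from the WT chromosome or is silent there, including through Zhx2 acting on the block alone, stays open without DNA data.

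The third pattern is that substrain differences travel with the genotype. Zhx2 had a log2 fold change of 4.65, and Afp, Gpc3 and Lpl, the 3 tested targets named in advance, had fitted values below 0, consistent with the known Zhx2 difference, although Gpc3 did not pass the test and Afp had the opposite sign with unstranded counts (0.77, not called) and did not pass with RSEM counts. The effect of Acads deficiency itself on any other gene is confounded with the substrain and was not tested. Among the 10 splits of the 6 libraries into 3 and 3, the real split alone, 1 of 10, called 947 genes, and the highest of the other 9 called 0 by edgeR. At an unadjusted p under 0.05 the others had 124 to 1197 genes against 3058, and 10 splits are too few for a share under 0.05. Each of the other splits also mixes the substrains within groups, which widens the spread there, so low counts follow from the real difference itself. They do not show what chance alone would give.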

How the results depend on the processing

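Leaving out the Mup genes and counting list members without each library were chosen after the data were seen, and the other alternatives before. The counts of 947 changed genes, 569 higher and 378 lower, stayed within 1.5 times under RLE and upper-quartile scaling, the CPM filter, DESeq2, limma-voom, edgeR without robust estimation, RSEM counts, the unstranded column, the replicate block and removal of Mup genes. Without a filter 1702 genes were called, 950 higher and 752 lower, with more genes tested. Against a 1.5-fold change 224 were called, 143 higher and 81 lower, a stricter question, under which Acads (-0.86, adjusted p = 0.244) did not pass. Over its other alternatives, single libraries left out included, the adjusted p of Acads stayed under 0.05, with log2 fold changes of -0.93 to -0.81 for the latter. Leaving out 1 library gave 395 to 1590 called genes, 240 to 909 higher and 155 to 681 lower. Upper-quartile scaling moved the median of all genes to -0.05 on the log2 scale.

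Of the 10 called lists, 0 were called with an estimated correlation (2 of 35 had an unadjusted p under 0.05) and 5 by fry, which called 6 lists in all. Fry tests a list against no change and camera against other genes. The cause was not tested. With an estimated correlation the adjusted p was 0.364 for amino acid and periportal genes, 0.371 for peroxisomal, PPAR-alpha, bile acid and lymphocyte genes, 0.571 for mitochondrial oxidation, 0.606 for gluconeogenesis and 0.617 for the unfolded protein response and endothelial markers. By fry it was 0.056 for mitochondrial oxidation, 0.107 for gluconeogenesis, 0.241 for the unfolded protein response, 0.0982 for endothelial and 0.0756 for lymphocyte markers, and 0.047 for the integrated stress response, which passed. Endothelial markers had 0.0788 with the CPM filter. Without Mup genes 0.0161 for male-biased and cholangiocyte genes and 0.000444 for Zhx2-regulated genes passed. Without 1 library the lists called numbered 11 to 14, and adjusted p ranged from 0.00329 to 0.0542 for mitochondrial oxidation, 0.000808 to 0.212 for gluconeogenesis, 0.016 to 0.155 for endothelial and 0.0148 to 0.204 for lymphocyte markers. The ranges were 0.016 to 0.342 for lipogenesis, 0.00427 to 0.933 for cholesterol, 0.00264 to 0.18 for Zhx2-regulated, 0.00264 to 0.798 for clock, 0.0193 to 0.868 for mitochondrial mRNAs and 0.000777 to 0.352 for interferon genes. For Kupffer, cholangiocyte and erythroid markers they were 0.0409 to 0.868, 0.0178 to 0.116 and 1.18e-05 to 0.381.

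Of 108 called named genes other than Acads, 49 passed under each alternative, 59 lost the call under at least 1, and Afp reversed to 0.77 with unstranded counts; the cause was not tested. A test against 1.5-fold ended 49 of those calls and leaving out WT replicate 2 ended 35. Without SCADD replicate 3, the library with most unmapped reads, 8 PPAR-alpha, 6 peroxisomal and 4 mitochondrial oxidation genes rose, and 7 amino acid, 5 bile acid, 4 periportal and 2 unfolded protein response genes fell.

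Replicate numbers are shared between the groups. Same-numbered libraries had correlations of 0.0606, 0.0372 and 0.107 of their deviations from the group means. Only the last was above the limit of 0.1. Deviations within a group sum to 0, so these correlations depend on each other, and whether the numbers pair animals stays open. SCADD replicates 2 and 3 correlated most with their own number and SCADD replicate 1 with WT replicate 2 (0.0612), while the other 5 differently numbered pairs were negative, from -0.127 to -0.0171. The replicate block called 1148 genes, 668 higher and 480 lower. Counts that moved included 5 mitochondrial oxidation, 9 PPAR-alpha and 1 ketone body genes higher, and 7 periportal and 2 acute-phase genes lower. Of amino acid genes 10 fell and 1 rose, and of gluconeogenesis and glycolysis genes 4 fell and 1 rose. With the block, de novo lipogenesis (0.00585) and Zhx2-regulated genes (0.00445) passed and endothelial markers (0.0598), Chac1 (0.0601) and H2-Q7 (0.0555) did not. At this depth 3 counts over the WT group were 0.0389 CPM, so levels under this could not be told from 0.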

Other observations

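Genes described here were chosen after their values were seen, except those taken by the naming rule, such as Acot1, Acot2, Acot3, Acot4 and Cyp2c54. Beyond the Mup genes, the largest rises included Nlrp12, an innate immune gene, from 0.421 ± 0.306 to 129 ± 38.4 CPM (SD, n = 3 each; edgeR adjusted p = 6.38e-05), and Mfsd2a, a lysophospholipid transporter, from 0.844 ± 0.502 to 49.8 ± 16.2 CPM (adjusted p = 0.000351). Vldlr, the very low density lipoprotein receptor, rose from 0.414 ± 0.141 to 20.5 ± 10.2 CPM (adjusted p = 0.000176). Clstn3 rose from 2.19 ± 0.997 to 42.9 ± 14.6 CPM (adjusted p = 0.000713), Gpc1 from 0.753 ± 0.143 to 12.8 ± 1.79 CPM (adjusted p = 3.89e-06) and Mogat1, a monoacylglycerol acyltransferase, from 0.449 ± 0.133 to 6.79 ± 1.38 CPM (adjusted p = 3.81e-05). Glo1, glyoxalase, rose from 288 ± 21.9 to 1044 ± 135 CPM (adjusted p = 0.000149). The thioesterase genes Acot1, Acot2, Acot3 and Acot4, related genes that share sequence, lie together on chromosome 12 and each rose in the main comparison.

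Changed genes lay near each other more often than chance. This was tested as written in advance, for linked substrain variants, which would group changed genes by position. Among 13467 placed genes, 127 neighbouring pairs were both called, against a mean of 65.7 and a 95th percentile of 78 in 10000 random orders (permutation p = 0.0001, the smallest these orders can give). Whether gene families in tandem are the whole cause was asked by a test also written before its result was seen. Without pairs whose symbols share their letters, 108 called pairs stayed against a 95th percentile of 74 (permutation p = 0.0001), and 99 against 72 when Mup genes were left out. Only letters before the first digit were compared, so Mup9 and Mup-ps4 counted as unrelated among the 108. Other related genes whose letters differ, such as Sds and Sdsl, can stay in both counts. Pairs with shared letters are thus not the whole cause, but tandem families with other letters are not excluded. Linked substrain variants may contribute, but related neighbours left in the counts, or shared regulation of unrelated neighbours, would give the same count. Neither was tested. Among windows of 10 neighbouring tested genes outside the Mup block, those with the most calls held 5. Those on chromosomes 1 and 6 each held 3 higher and 2 lower genes. In the window on chromosome 19, from 39608842 to 40271842, Cyp2c67, Cyp2c68, Cyp2c54, Cyp2c70 and Pdlim1 were lower. All but Pdlim1 belong to the Cyp2c family.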
